A study of Homo sapiens with 3 samples.

How the data were processed

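RNA libraries from UM-UC-3 cells were compared, 1 with control siRNA and 2 with different NONO siRNAs, each at 75 nM for 48 h. The labels put both knockdown libraries in a single NONO group, and nothing in them says whether the libraries come from separate cultures. bcl2fastq 2.19.1, HISAT2 2.1.0 and HTSeq 0.6.1 and the builds hg19 and GRCh37 are named per the submitters' processing notes, without roles or order, and the annotation release and strand setting are not given in the sources used here. The authors deposited 1 table per library with normalized values, and the values themselves show that these are CPM without length normalization. Each column sums to slightly less than the CPM total, and 99.3%, 99.3% and 99.5% of values in the control, siRNA 1 and siRNA 2 libraries are whole multiples, within 0.01 reads, of the CPM of 1 read. The remaining 147, 147 and 117 genes sit at exactly 0.5 of a read and were taken as 0 reads. The implied totals were 27681990, 29408573 and 28594569 reads, of which 3950, 4533 and 4897 were not in listed genes. The tables list 22281, 22281 and 22464 genes, and the 21308 genes in all 3 were used. A gene missing from a table reached at most 0.578 CPM elsewhere.

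Since the values are normalized, the main test was limma 3.58.1 with a trend, in R 4.3.3, on log2(CPM + 1), as laid down before the data were examined for that case. Genes with at least 1 CPM in at least 1 library were kept, which left 13922. The 2 siRNA libraries were set against the lone control library, which leaves 1 residual degree of freedom with 7.68 prior degrees of freedom from all genes. P-values therefore rest on the spread between 2 different siRNAs, which includes their off-target differences, and assume that the lone control library varies alike. Most of each gene's variance comes from the trend over all genes, so SEs and p-values do not show how well the siRNAs agreed on that gene. P-values were two-sided, were adjusted by the Benjamini-Hochberg method and were called under 0.05. Folds are on the log2(CPM + 1) scale, which understates changes of genes near 1 CPM, and fold values for a single siRNA have no replicate check. Poisson intervals are exact at 95% and, as read pairs are not independent molecules, cover counting error only.

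As an addition made after the units were known, edgeR 4.0.16 (quasi-likelihood, TMM, 16963 genes) and DESeq2 1.42.0 were run on the recovered reads and called 151 and 198 genes. On simulated data with 200 changed genes in each of 5 rounds, over a mean of 13720 genes, limma in this comparison of NONO siRNA with control recovered 58.1% of 2-fold, 100% of 4-fold and 100% of 8-fold changes, and 5.97% of its calls were false. edgeR recovered 56.2%, 100% and 100%, with 4.87% false. The simulated libraries varied by 1 common dispersion, which real differences between siRNAs need not follow. These rates therefore need not hold for the real libraries, where IFIT3, with a mean log2 fold of -2.14, was not called by limma.

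Before the data were examined, 27 gene lists were fixed. For each, the members passing the test were counted over all genes and adjusted over the list alone, and the median fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description without a p-value. Genes were named by a rule fixed at the same time. It took NONO, SETMAR, SFPQ, PSPC1 and NEAT1, then the 10 highest and 10 lowest called genes by the smaller of the 2 absolute log2 folds, with a mean of at least 5 CPM, then up to 4 members of each list with called members first, and the 5 highest and 5 lowest ratios of siRNA 1 over siRNA 2. Some genes that the rule took are not reported here. Symbols came from a name table that held 21049 of the gene identifiers, and 21182 were in GENCODE 29. Coordinates are those of GENCODE 29 on GRCh38 and of matches of the siRNA sequences to it, not of the build named in the notes. Reads of genes with near-identical copies, such as histones, ribosomal proteins and their pseudogenes, and of overlapping or antisense genes are uncertain.

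The sequences in the labels of both NONO siRNAs match NONO transcripts and are thus sense strands, and the control sequence was taken the same way. If the control's label gives its antisense strand instead, every value given for its sense-strand site belongs to its guide strand and the reverse. Seed sites are the 7 bases complementary to positions 2 to 8 of a strand. They were searched in 1 transcript per gene, with a 3' UTR of at least 50 bases, for 11512 of 11797 protein-coding genes tested (97.6%). Random lists for sites were matched on expression and on 3' UTR or transcript length. To describe unchanged libraries that share a control, 100 draws took each gene's spread from a trend of the difference between both siRNAs over expression, or, for overlaps, also from that gene's own difference. Alternatives were upper-quartile and TMM scaling, other filters and pseudocounts, limma without a trend, the count tests, each siRNA alone, other seed lengths and exonic length. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Exon use was not analysed here, since the values are gene totals.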

Results

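NONO is an RNA- and DNA-binding protein of the DBHS family that takes part in transcription, pre-mRNA splicing and the building of nuclear paraspeckles. Its knockdown was measured by RNA sequencing in UM-UC-3 cells, a human bladder cancer line. The study asked how NONO acts on SETMAR splicing and on lymphatic spread. Cells received 75 nM of a control siRNA or of either of 2 independent NONO siRNAs for 48 h, and each treatment gave 1 library of 100 bp paired-end reads. The values implied 27681990 reads on genes in the control library, 29408573 with NONO siRNA 1 and 28594569 with NONO siRNA 2. Of the genes listed in all 3 libraries, 13922 reached 1 CPM, a read count scaled to the library total, in at least 1 of them and were tested.

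NONO itself was far lower in both knockdown libraries. NONO (ENSG00000147140, GRCh38 chromosome X, 71283192 to 71301168, plus strand) stood at 823 CPM in the control library (95% Poisson interval 813 to 834). It stood at 79.5 CPM with siRNA 1 (76.3 to 82.8) and at 104 CPM with siRNA 2 (99.8 to 107). These levels were 9.66% and 12.6% of the control. The log2 folds were -3.36 and -2.98, with an SE of 0.24 for their mean, and NONO passed limma's test (adjusted p = 0.00698). The siRNA 1 target, GGCGAAGTCTTCATTCATA, lay in coding exon 3 of the 11 exons of transcript NONO-202, at X:71291925 to 71291943. The siRNA 2 target, GCATCCCTTACAGTTCGAA, lay in coding exon 4 at X:71294320 to 71294338. Both targets also matched 1 non-coding transcript on chromosome 16, AC092115.1-201, at 69757632 to 69757650 and at 69757491 to 69757509. The control siRNA's sequence as labelled matched no annotated transcript over its full length, and its reverse complement was not searched.

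SETMAR, a gene that joins a histone methyltransferase domain to a transposase domain, had log2 folds of opposite sign with the 2 siRNAs. SETMAR (ENSG00000170364, chromosome 3, 4303304 to 4317567, plus strand) gave 134 reads in the control library, or 4.84 CPM (95% Poisson interval 4.06 to 5.73). It gave 196 reads, or 6.66 CPM, with siRNA 1 (5.76 to 7.67) and 107 reads, or 3.74 CPM, with siRNA 2 (3.07 to 4.52). The siRNA 2 interval overlaps that of the control, and the intervals cover counting error only. The log2 folds were 0.39 and -0.30, and SETMAR did not pass limma's test (adjusted p = 0.975). These are gene totals, which do not show which exons were used, so SETMAR splicing was not measured here.

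The partners of NONO were somewhat more abundant in both knockdown libraries without passing the test. PSPC1, a DBHS paralog of NONO, had log2 folds of 0.45 and 0.83 over a control level of 78.5 CPM. SFPQ, the other paralog, had 0.33 and 0.56 over 649 CPM. NEAT1, the RNA on which paraspeckles form, had 0.52 and 0.85 over 506 CPM. The limma adjusted p was 0.384 for PSPC1, 0.452 for SFPQ and 0.256 for NEAT1. Over the fixed list of 16 paraspeckle components and partners, which left out NONO, 11 were higher and 5 lower with both siRNAs, and none passed the test, also when adjusted over the list alone. The list's median log2 folds of 0.076 and 0.10 lay at percentiles 79.2 and 82.05 of random lists matched on expression.

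**Figure D1:**
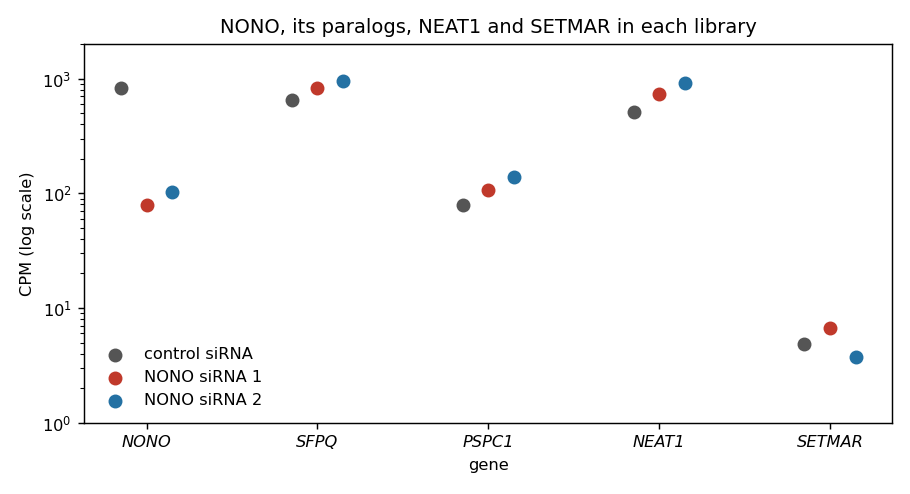
CPM on a log axis of NONO, SFPQ, PSPC1, NEAT1 and SETMAR, with 1 point per library and no replicate libraries. NONO stands at 823 CPM in the control library and at 79.5 and 104 CPM in the knockdown libraries, while SETMAR lies between 3.74 and 6.66 CPM.

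Among all genes, 19 rose and 11 fell with NONO siRNA at an adjusted p under 0.05 in limma, and 1588 genes had an unadjusted p under 0.05. The genes that rose were not of a single kind. GANAB, the catalytic subunit of glucosidase II in the endoplasmic reticulum, went from 164 CPM to 755 and 761 CPM (log2 folds 2.20 and 2.21, SE 0.20, adjusted p = 0.0102). TPM4, a tropomyosin of the actin cytoskeleton, went from 247 CPM to 995 and 1246 CPM (2.01 and 2.33, SE 0.22, adjusted p = 0.0125). SETD7, a lysine methyltransferase, had log2 folds of 2.68 and 2.13 over a control level of 30.5 CPM. KIF1C, a kinesin, had 1.91 and 2.13 over 72.8 CPM, and CDK14, a cyclin-dependent kinase, had 1.88 and 2.27 over 13.5 CPM. ICMT, which methylates prenylated proteins, and the transcription factor FOXP4 had log2 folds between 1.78 and 1.84. The protocadherin PCDH10 and the zinc finger gene ZNF76 started at 5.42 and 4.88 CPM and rose by log2 folds of 1.86 to 2.33. Of the genes named in this direction, SETD7, TPM4, KIF1C, CDK14, ICMT, FOXP4 and ZNF76 hold the 7-base seed site of the control siRNA's sense strand in their transcript.

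The genes that fell were of several kinds, among them a protease, signalling genes and a tetraspanin. MMP9, a gelatinase that degrades basement membrane collagen, had the lowest fold of all genes called, from 124 CPM to 2.11 and 5.18 CPM (log2 folds -5.33 and -4.34, SE 0.40, adjusted p = 0.00698 in limma). TRAF1, an adaptor of TNF receptor signalling, went from 73.6 CPM to 7.28 and 9.41 CPM (-3.17 and -2.84, adjusted p = 0.0105 in limma). NFKBIE, an inhibitor of NF-kB, went from 41.8 CPM to 10.1 and 10.5 CPM. IFIT2, an interferon-induced antiviral gene, had log2 folds of -3.30 and -2.65, and SOCS1, a feedback inhibitor of cytokine signalling, had -2.38 and -2.25. CD82, a tetraspanin known as a metastasis suppressor, had -2.99 and -2.28 over a control level of 107 CPM. SBSN, coding for suprabasin, had -3.45 and -2.51, DTX4, a ubiquitin ligase gene, had -2.13 and -2.04, and TLCD3A had -2.01 and -2.02. MMP9, DTX4 and TLCD3A hold the seed site of NONO siRNA 1 in their transcript, and DTX4 also the control sense-strand site.

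The number of calls depended on the settings of the test. With TMM scaling of the recovered reads limma called 1 gene higher and 3 lower, with upper-quartile scaling 161 higher and 80 lower, and with no filter on low values it called none, NONO included, while edgeR on the recovered reads called 86 higher and 65 lower, among them all 30.

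**Figure D2:**
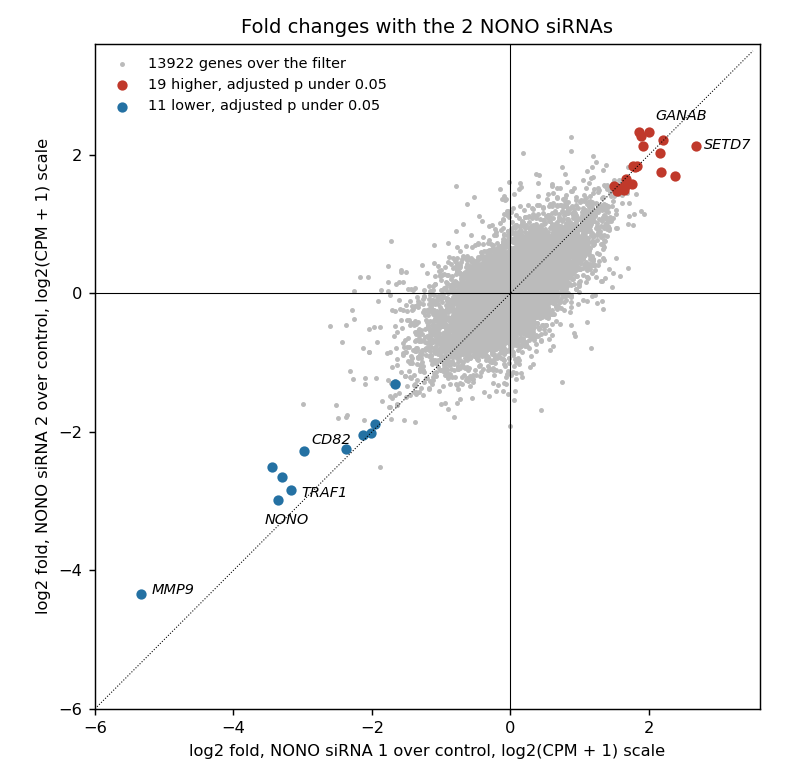
Log2 fold of each of 13922 genes over the control library, with NONO siRNA 1 on the horizontal and NONO siRNA 2 on the vertical axis, both on the log2(CPM + 1) scale. Red and blue points are the 19 genes called higher and the 11 called lower, the dotted line marks equal folds, and MMP9 stands lowest at -5.33 and -4.34.

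Inflammatory genes stood lower as a group in both knockdown libraries. All 16 measured members of the fixed list of cytokines and NF-kB targets were lower with both siRNAs, and 12 fell when adjusted over the list alone, although none passed the limma test adjusted over all genes. The list's median log2 folds were -1.34 with siRNA 1 and -0.96 with siRNA 2, below all 10000 matched random lists. NFKBIA, the inhibitor that NF-kB induces in its own feedback, went from 226 CPM to 78.8 and 79.1 CPM, and NFKB2, an NF-kB subunit, went from 235 CPM to 89.9 and 93.9 CPM. The chemokines CCL2 and CCL5 had log2 folds of -1.38 and -1.86, and of -2.11 and -1.83. Adjusted over all genes, the limma p of these genes lay between 0.0507 for NFKBIA and 0.0761 for CCL2, and edgeR called 5 of the list's members lower.

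Interferon-stimulated genes showed a like direction. Of 20 measured members 18 were lower with both siRNAs, IFIT2 fell over all genes tested, and 9 fell when adjusted over the list alone. Their median log2 folds of -0.96 and -0.60 also lay below all matched random lists. The list was fixed also as a sign of a response to transfected RNA. With a lone control library, a response of the control culture to its siRNA and an effect of the knockdown cannot be told apart. IFIT3 went from 30.9 CPM to 4.69 and 8.15 CPM, and OASL from 5.71 CPM to 0.306 and 0.979 CPM. IRF1, a transcription factor of the interferon response, had log2 folds of -1.33 and -1.43. Adjusted over the list alone, the limma p was 0.00156 for IFIT3, 0.00156 for OASL and 0.00331 for IRF1.

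**Figure D3:**
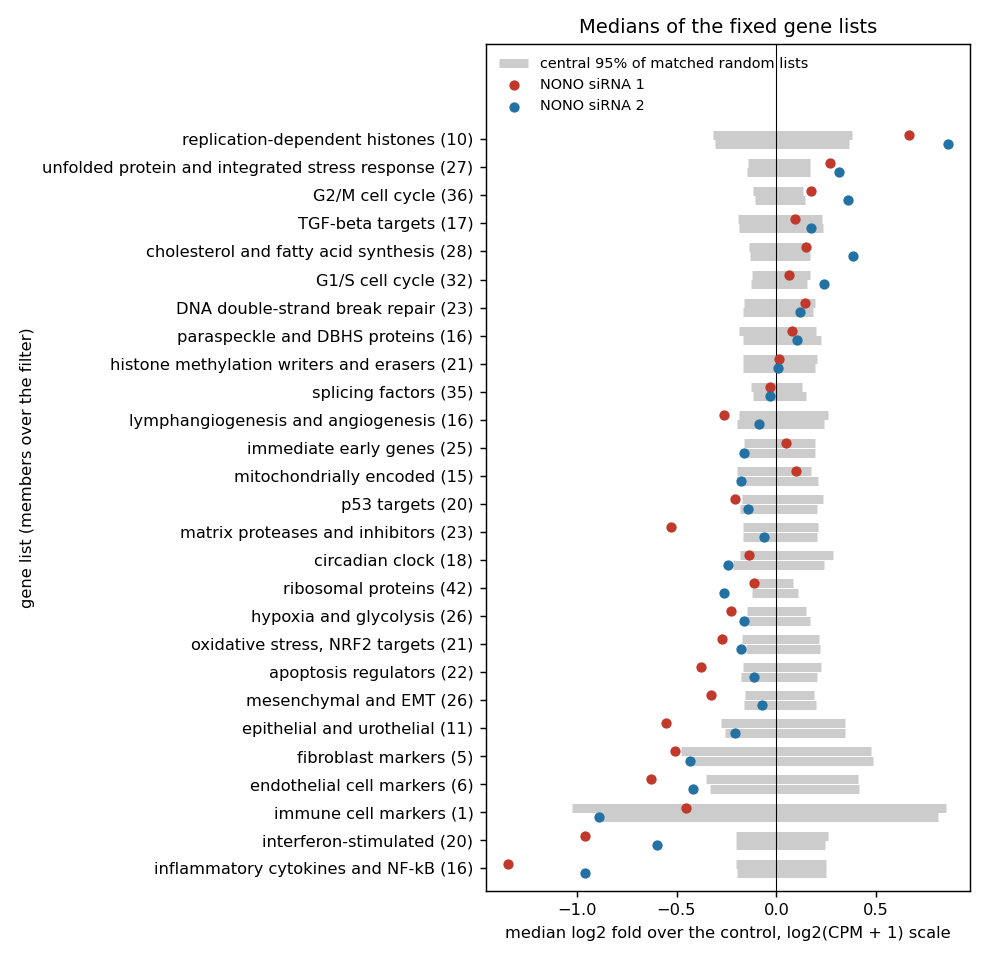
Median log2 fold over the control library of each of 27 fixed gene lists, on the log2(CPM + 1) scale, with siRNA 1 in red and siRNA 2 in blue. Grey bars are the central 95% of medians of matched random lists, and the inflammatory list lies lowest at -1.34 and -0.96.

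Genes of matrix remodelling and cell identity were mostly lower with siRNA 1 and less clearly with siRNA 2. Of 23 matrix proteases and inhibitors, MMP9 fell over all genes, and adjusted over the list alone 3 fell and 1 rose. PLAU, the urokinase protease, went from 1635 CPM to 500 and 782 CPM, and MMP14, a membrane-bound collagenase, from 708 CPM to 370 and 381 CPM, and both fell when adjusted over the list alone. MMP3 rose when adjusted in the same way, from 1.26 CPM to 3.26 and 4.09 CPM. The list's medians were -0.53 (percentile 0) and -0.062 (percentile 22.1). Of 26 mesenchymal and EMT genes none passed limma's test, also when adjusted over the list alone, and their medians were -0.33 (percentile 0) and -0.072 (percentile 17.6). SPARC, a matricellular protein, had log2 folds of -1.23 and -0.80, and ITGA5, the fibronectin receptor subunit, had -0.82 and -0.67. The 11 epithelial and urothelial genes had medians of -0.55 (percentile 0.08) and -0.21 (percentile 6.05), with no member passing, and CLDN1 of tight junctions had log2 folds of -1.11 and -0.49. Of the lower genes named here, MMP9, MMP14 and SPARC hold the seed site of NONO siRNA 1 in their transcript and ITGA5 that of siRNA 2. MMP14 also holds the control sense-strand site, and PLAU and CLDN1 hold none of these.

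No member of the 16 measured lymphangiogenesis and angiogenesis genes passed the test, also when adjusted over the list alone. Their medians were -0.26 with siRNA 1 (percentile 0.45) and -0.088 with siRNA 2 (percentile 16.7). VEGFA, the main vascular growth factor, went from 177 CPM to 124 and 141 CPM, PGF, a growth factor of the same family, had log2 folds of -0.99 and -0.45, and ANGPT1, a ligand of the TEK receptor, had 0.39 and 0.78.

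Mitotic genes stood higher in both knockdown libraries. Of 36 G2/M genes 29 were higher with both siRNAs, and 2 rose when adjusted over the list alone. Over all genes limma called none of them and edgeR 1 higher. Their medians were 0.17 (percentile 99.4) and 0.36 (percentile 100). BIRC5, the mitotic inhibitor of apoptosis survivin, went from 64.9 CPM to 165 and 172 CPM (limma p adjusted over the list alone 0.00809). CENPF, a kinetochore protein, went from 164 CPM to 304 and 328 CPM (0.0332). Both hold a seed site of a control siRNA strand in their transcript. The 32 G1/S genes had medians of 0.065 (percentile 72.5) and 0.24 (percentile 99.8) with no member passing, and E2F1, which holds the control sense-strand site, had log2 folds of 1.01 and 0.62. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, also stood higher. Of 10 measured, 9 were higher with both siRNAs and 6 rose when adjusted over the list alone, with none called over all genes by limma or edgeR and medians of 0.66 (percentile 99.97) and 0.86 (percentile 100). H2BC11 went from 1.01 CPM to 4.08 and 3.81 CPM. Histone genes are near-identical in sequence, so values of single members are uncertain. Of 20 p53 targets 2 fell when adjusted over the list alone, CDKN1A, an inhibitor of cyclin-dependent kinases, from 477 CPM to 165 and 208 CPM, and GADD45A, a stress-response gene, from 141 CPM to 71.4 and 55.2 CPM. The p53 list's medians were -0.21 (percentile 1.03) and -0.14 (percentile 6.67), and over all genes limma called none of its members and edgeR 2 lower.

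Sterol and stress-response genes were higher on the whole. Of 28 genes of cholesterol and fatty acid synthesis 17 were higher with both siRNAs, with medians of 0.15 (percentile 97.0) and 0.38 (percentile 100). Of these 1 rose when adjusted over the list alone. INSIG1, which restrains sterol synthesis, went from 125 CPM to 61.9 and 70.5 CPM and did not pass. Of 27 genes of the unfolded protein and integrated stress responses 19 were higher with both siRNAs, with medians of 0.27 (percentile 99.86) and 0.31 (percentile 99.95). The chaperone CALR, the pseudokinase TRIB3 and the serine synthesis enzyme PHGDH rose when adjusted over the list alone, CALR from 498 CPM to 1015 and 818 CPM. No member of either list passed over all genes.

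Splicing factors as a group stayed close to the control. None of 35 measured members passed limma's test, also when adjusted over the list alone, and 13 were higher and 16 lower with both siRNAs. Their medians were -0.033 and -0.032, at percentiles 34.0 and 27.4. PTBP1, a repressor of exon inclusion, had log2 folds of 0.59 and 0.65, and its paralog PTBP2 had -0.58 and -0.68, with adjusted p values of 0.259 and 0.356 in limma. No member of the 21 histone methylation enzymes passed, with medians of 0.014 (percentile 50.8) and 0.0096 (percentile 53.6). KDM2A and KDM2B had log2 folds between 0.73 and 0.99, and both hold the control sense-strand site. The 23 genes of DNA double-strand break repair had medians of 0.14 (percentile 91.7) and 0.12 (percentile 90.4) with no member passing, and XRCC4, an end-joining factor, had log2 folds of 1.15 and 1.07.

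Signs of RNA quality and of other cell types were read alongside. The 42 ribosomal protein genes had medians of -0.11 (percentile 4.31) and -0.26 (percentile 0), and 36 of them were lower with both siRNAs, none passing the test. RPS4X went from 2202 CPM to 1783 and 1447 CPM. The 15 mitochondrially encoded genes had medians of 0.10 (percentile 89.8) and -0.18 (percentile 4.0), and the mitochondrial share of all reads was 6.83% in the control library, 7.35% with siRNA 1 and 6.14% with siRNA 2. Of the leukocyte markers only ITGAM was measured, at 1.30 CPM or less. The 6 endothelial markers had medians of -0.63 (percentile 0.14) and -0.42 (percentile 0.99), with TIE1, an endothelial receptor, at 55.7, 15.4 and 30.2 CPM in the control, siRNA 1 and siRNA 2 libraries and a fall when adjusted over the list alone. The 5 fibroblast markers had medians of -0.51 (percentile 1.87) and -0.43 (percentile 2.5), and THY1 stood at 22, 14.0 and 16.0 CPM.

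The 2 siRNAs moved genes alike to a degree. At least 2-fold higher with both were 173 genes, of 354 with siRNA 1 and 328 with siRNA 2, and at least 2-fold lower with both were 93 genes, of 379 and 199. Simulated unchanged libraries that share 1 control gave a mean of 67.1 higher (50 to 87 over 100 draws) and 69.6 lower (54 to 89) where each gene kept its own spread, and 7.19 and 7.45 where the spread followed expression. No gene was 2-fold higher with one siRNA and 2-fold lower with the other, against means of 8.79 and 0. With a pseudocount of 0.1 the observed counts were 338 higher and 194 lower, and with a mean of at least 5 CPM 59 were lower. Without genes that hold a site of either control siRNA strand, 102 were higher, genes that were not searched staying in. Across the 13922 genes, which are not independent replicates, the log2 folds had a Pearson r of 0.671 and a Spearman rho of 0.631. The simulation with spread by expression gave 0.499 and 0.481. The covariance was 0.15 against 0.0740 simulated, a difference of 0.0759, and 72.3% of genes had the same sign against 66.5% simulated. The single control library cannot be divided, so its share in this excess was not measured.

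The siRNAs also differed from each other, with no replicate to test it. On the rule of size 80 genes were at least 2-fold higher and 205 at least 2-fold lower with siRNA 1 than with siRNA 2, and 212 and 442 with a pseudocount of 0.1. SPCS3, a signal peptidase subunit, stood at 168 CPM in the control library, 36.6 CPM with siRNA 1 and 199 CPM with siRNA 2. UHMK1, a kinase, stood at 338, 70.0 and 346 CPM in the same order, and NPTN, coding for neuroplastin, at 74.7, 17.2 and 88.2 CPM. FGF1 and MAPK6 differed on both sides of the control, with log2 folds of -1.73 and 0.76 for FGF1 and of -0.79 and 1.55 for MAPK6. COLGALT1, a collagen galactosyltransferase, stood at 223 and 222 CPM in the control and siRNA 1 libraries and at 58.3 CPM with siRNA 2. TBC1D1, RHOB, SHH and DUSP4 were likewise lower with siRNA 2 than with siRNA 1, by 1.59 to 2.12 on the log2 scale. SPCS3, UHMK1, NPTN, FGF1 and MAPK6 hold the siRNA 1 seed site in their transcript, and so do COLGALT1 and DUSP4. FGF1 and MAPK6 also hold the sites of both control siRNA strands. TBC1D1 and DUSP4 hold the siRNA 2 site, TBC1D1 also the control sense-strand site, and RHOB and SHH hold none of these.

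Seed sites were searched because an siRNA can lower transcripts that pair with bases 2 to 8 of a strand. Of 11512 searched genes 1748 hold the siRNA 1 site CATTCAT in the 3' UTR, and their median log2 ratio of siRNA 1 over siRNA 2 was -0.17, below all 10000 random lists matched on expression and 3' UTR length. Of the genes at least 2-fold lower with siRNA 1 than with siRNA 2, 81 of 180 searched (45%) hold this site in the 3' UTR, against 18.9% to 30.6% in the central 95% of matched lists. The 531 genes with the siRNA 2 site AGTTCGA had a median of 0.042 for the same ratio, above all matched lists, while their siRNA 2 over control median of -0.0018 lay within the range. That median was below the range with the 6-base site (-0.027), with the 8-base site (-0.36) and with the 7-base site anywhere in the transcript (-0.069). The 1485 genes with the site AGGGATG of the siRNA 2 sense strand had a siRNA 2 over control median of -0.022, below all matched lists. With its 6-base site the median (-0.012) was also below them, but with the 8-base site (-0.021) and anywhere in the transcript (-8.5e-05) it lay within the range. Lists were not matched on GC content, with which siRNA 2 folds had a Spearman rho of -0.19. The 171 genes with the site ACTTCGC of the siRNA 1 sense strand had a siRNA 1 over control median of -0.034, within the range. Of the lower genes named above whose sites were not given, GADD45A and INSIG1 hold the siRNA 1 site CATTCAT in their transcript. CCL5, IRF1, VEGFA, RPS4X and TIE1 hold the siRNA 2 site AGTTCGA. INSIG1 and TIE1 also hold the control sense-strand site.

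Sites of the control siRNA went with higher levels in the knockdown libraries. The 229 genes with the site TCGGAGA of its sense strand in the 3' UTR had a median log2 fold of 0.12, and the 341 with the site TGTCACG of its guide strand had 0.093, both above all matched lists. With 8-base sites the sense strand gave 0.28, again above all matched lists, and the guide strand -0.00065, within the range. Anywhere in the transcript, the sense-strand site was present in 54 of 154 searched genes at least 2-fold higher with both siRNAs (35.1%), where matched lists gave 7.79% to 17.5%. Of the 19 genes called higher, 11 held it (57.9%, against 0 to 26.3%), and of 91 searched genes at least 2-fold lower with both, 14 held it (15.4%, against 5.49% to 17.6%). The genes called higher with the site were CDK14, CLIP1, FOXP4, GPAA1, ICMT, KIF1C, NOLC1, SETD7, TOMM22, TPM4 and ZNF76, of which CLIP1, GPAA1, NOLC1 and TOMM22 were named after their values were seen. Leaving genes with a site of either control strand out of the count, without a new fit, left 8 genes called higher and 10 lower. Of the 154 searched genes at least 2-fold higher with both, 83 held neither site (53.9%, against 82.6% of all searched genes). Which strand of the control siRNA is the guide rests on reading its label as the sense strand.

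**Figure D4:**
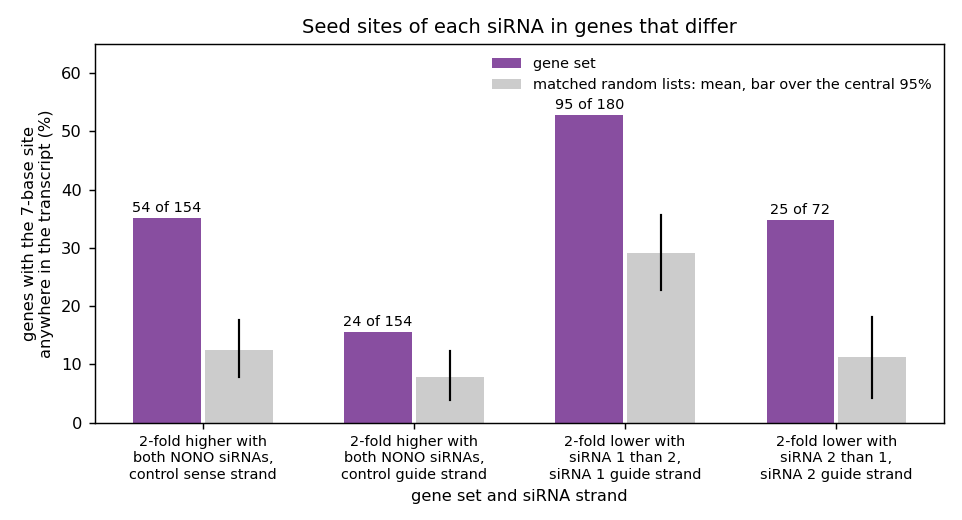
Percent of searched genes in 4 gene sets that hold the 7-base seed site of the named siRNA strand anywhere in the transcript, in purple, beside the mean of matched random lists in grey with a line over their central 95%. The control sense-strand site is in 54 of 154 genes higher with both NONO siRNAs and the siRNA 1 site in 95 of 180 genes lower with siRNA 1 than with siRNA 2.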

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

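The alternatives with TMM scaling, edgeR, DESeq2 and without genes holding a control siRNA site were chosen after seeing the data. The last of these only leaves genes out of the counts and list medians of the main fit, without a new fit or adjustment. All 20 called genes that the naming rule took kept their sign in 8 alternatives, and 20 stayed called with upper-quartile scaling, edgeR and DESeq2, 19 with a pseudocount of 0.1, 5 with a mean of at least 5 CPM, 4 with TMM scaling, 3 without a trend and 0 with no filter. No call named here turned its direction, while 4 list medians near 0 changed sign. These were histone methylation, immediate early (-0.050 to 0.046) and mitochondrially encoded genes (-0.056 to 0.10) with siRNA 2 left out, the first also with siRNA 1 left out, and lymphangiogenesis (-0.031 to 0.013) with a mean of at least 5 CPM and without genes holding a control site. Calls higher and lower were 161 and 80 with upper-quartile scaling, 138 and 60 with DESeq2, 86 and 65 with edgeR, 8 and 10 without genes holding a control site, 2 and 3 with a mean of at least 5 CPM, 0 and 3 without a trend, 1 and 3 with TMM scaling, and 0 and 0 with no filter, where 1882 genes had an unadjusted p under 0.05. The scale factors of the upper-quartile alternative lay within 0.994 to 1.01, while limma's prior degrees of freedom went from 7.68 to 16.7 with it and to 2.52 with no filter. The cause of these changes in calls was not tested. With siRNA 1 or siRNA 2 as the lone library, limma called 0 and 0 genes each, with 602 and 281 unadjusted. NONO kept its log2 fold of -3.17 with no filter but not its call (limma adjusted p = 0.566). Its adjusted p over the alternatives ran from 1.35e-19 with DESeq2 to that value. Genes at least 2-fold higher and lower with both siRNAs were 338 and 194 with a pseudocount of 0.1, and 102 were higher without genes holding a control site, where genes that were not searched stay in, and 59 lower with a mean of at least 5 CPM. Leaving out either siRNA, which leaves 1 library against 1 and no test, gave 328 to 354 higher and 199 to 379 lower. Between the siRNAs, 212 and 442 genes differed with a pseudocount of 0.1.

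List medians moved as follows, and the cause was not tested. With DESeq2, edgeR and TMM scaling they were 0.059, 0.061 and 0.067 for paraspeckle proteins, -0.040, -0.038 and -0.032 for splicing factors, -0.038, -0.036 and -0.029 for histone methylation enzymes and 0.067, 0.069 and 0.074 for double-strand break repair. With DESeq2 and edgeR they were 0.97 and 0.97 for histones, -1.52 and -1.51 for immune and -0.58 and -0.58 for fibroblast markers. A pseudocount of 0.1 gave 0.97 for histones and -1.43 for immune markers. A mean of at least 5 CPM gave -0.027 for splicing factors, -1.13 for interferon-stimulated genes, 0.61 for histones and -0.26 for fibroblast markers. Upper-quartile scaling gave -0.025 for splicing factors and -0.022 for histone methylation enzymes. Without genes holding a control site, they were -0.026 for histone methylation enzymes, -0.18 for p53 targets, -0.28 for circadian genes, -0.27 for hypoxia genes, 0.13 for double-strand break repair and -0.26 for fibroblast markers. Leaving out either siRNA gave -0.033 to -0.032 for splicing factors, 0.0096 to 0.014 for histone methylation enzymes (-0.0091 with both), -0.26 to -0.088 for lymphangiogenesis, -0.53 to -0.062 for proteases, -0.21 to -0.14 for p53 targets, 0.27 to 0.31 for the stress responses, 0.094 to 0.18 for TGF-beta targets, 0.12 to 0.14 for double-strand break repair, -0.63 to -0.42 for endothelial and -0.51 to -0.43 for fibroblast markers. The siRNA 2 site went below the matched range of siRNA 2 over control at 6 bases (-0.027) and 8 bases (-0.36), and the control guide site went into its range at 8 bases (-0.00065). Spearman rho with exonic length was -0.069 for siRNA 1, 0.044 for siRNA 2 and -0.018 for the mean. The planned size factors and total counts for count tables were not run as such, since the files hold CPM, which are already per total. Low read numbers limit genes such as SETMAR, whose siRNA 2 interval overlaps that of the control. No paired analysis was possible because the control group has a single library.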

Other observations

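Further fixed lists had no member that passed limma's test over all genes. Of 25 immediate early genes 4 fell and 1 rose when adjusted over the list alone. JUNB, a subunit of the AP-1 transcription factor, went from 48.8 CPM to 16.1 and 13.0 CPM, and DUSP6, a phosphatase that limits ERK signalling, from 77.3 CPM to 42.6 and 38.8 CPM. KLF6, a zinc finger transcription factor, rose from 154 CPM to 337 and 293 CPM. The list's medians were 0.046 with siRNA 1 and -0.16 with siRNA 2. Of 17 TGF-beta targets 2 fell when adjusted over the list alone, with medians of 0.094 and 0.18. SMAD7, an inhibitor of the pathway, went from 25.5 CPM to 9.79 and 9.30 CPM. Of 18 circadian genes 2 fell when adjusted in the same way, PER1 with log2 folds of -0.95 and -1.18 and BHLHE41 with -1.18 and -1.38, and the medians were -0.14 and -0.24.

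Of 26 hypoxia and glycolysis genes 15 were lower with both siRNAs, with medians of -0.23 (percentile 0.17) and -0.16 (percentile 1.24). The glucose transporter SLC2A1 went from 352 CPM to 209 and 220 CPM without passing, while PFKL, a phosphofructokinase that holds the control sense-strand site, rose when adjusted over the list alone with log2 folds of 1.12 and 1.09. The 21 NRF2 targets had medians of -0.27 (percentile 0.1) and -0.18 (percentile 1.25), with AKR1C1 at log2 folds of -1.05 and -0.60. The 22 apoptosis regulators had medians of -0.38 (percentile 0) and -0.11 (percentile 10.8), and MCL1, an inhibitor of apoptosis, went from 390 CPM to 249 and 225 CPM. No member of the NRF2 and apoptosis lists passed, also when adjusted over the list alone. Across genes, Spearman rho of the log2 fold with genomic length was -0.056 for siRNA 1, 0.079 for siRNA 2 and 0.0090 for their mean, and with exonic GC content 0.039, -0.19 and -0.080.

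The tests of library scaling, of control sense-strand and siRNA 2 sites anywhere in the transcript, of sites as the whole cause, and of a response of the control culture were chosen only after the results were seen, and the tests of 3' UTR sites were chosen before. The genes at least 2-fold higher with both NONO siRNAs may owe part of their difference to the control siRNA lowering them in the control library. The site of its guide strand was in the 3' UTR of 7.79% of searched members (matched lists 0.649% to 6.49%), that of its sense strand in 10.4% (0 to 5.19%), and the sense-strand site was anywhere in the transcript of 35.1% (7.79% to 17.5%). In the 3' UTRs it ranked 1 of 16032 sites, and none of 179 sites of the same bases was as frequent in these transcripts, the highest reaching 19.5%. Of searched members, 64.9% hold no sense-strand site and 53.9% no site of either strand, against 82.6% of all searched genes. These shares argue only against direct pairing at these sites in each member as the whole cause. Genes with the 6-base sites in the 3' UTR also stood above all matched lists. Their median log2 folds were 0.093 for the sense and 0.070 for the guide strand. An effect passed on from other genes needs no site in the members. For members without a site, both the control siRNA and the knockdown of NONO stay open. The TMM factors, which left the median log2 fold of the 2-fold higher genes at 1.25, were too close to 1 to test scaling. The median log2 folds over all tested genes were 0.025 and 0.0073, but CPM sets each library to the same total. A shift of total RNA would therefore not show in them. A scale factor moves all genes of a library alike, which argues only against scaling as what sets these genes apart from the median gene.

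The lower inflammatory and NF-kB genes are a candidate response to the loss of NONO or a state of the lone control culture. Of the 6 members at least 2-fold lower with both, 0 hold the siRNA 1 site in the 3' UTR (matched lists 0 to 33.3%) and 1 that of siRNA 2 (16.7%, 0 to 16.7%), too few to exclude seed effects on single members. Anywhere in the transcript 25% of the 16 members hold the siRNA 1 site (0 to 31.2%) and 18.8% that of siRNA 2 (0 to 18.8%). The 75% without the siRNA 1 site argue only against direct pairing of its seed with each member as the whole cause. An effect passed on from other genes needs no site in the members, so the seed as a cause is not excluded. With TMM scaling the list's median log2 fold was -1.20, but those factors were too close to 1 to test scaling. The median log2 folds over all tested genes were 0.025 and 0.0073, but CPM sets each library to the same total. A shift of total RNA would therefore not show in them. A scale factor moves all genes of a library alike, which argues only against scaling as what sets the list apart from the median gene. The list's median log2 ratio of siRNA 1 over siRNA 2 was -0.22, small beside its medians against the control of -1.34 and -0.96. A response of the control culture, for example to its siRNA, and an effect of the knockdown cannot be told apart, because there is 1 control library.

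The genes that differed between the NONO siRNAs may in part be seed targets of each siRNA. Of genes at least 2-fold lower with siRNA 1 than with siRNA 2, 45% hold the siRNA 1 site in the 3' UTR (matched lists 18.9% to 30.6%). In the 3' UTRs it ranked 2 of 16192 sites. Anywhere in the transcript it was in 52.8%, and the highest of 209 other sites of the same bases reached 52.2%. The lists were not matched on GC content. Genes under 40% GC had median log2 folds of -0.032 with siRNA 1 and 0.13 with siRNA 2, so base composition was not told apart from seed pairing. The same search of 3' UTRs for siRNA 2 gave 9.72% (1.39% to 11.1%). That leaves a part of 3' UTR sites open for siRNA 2, as genes with its 8-base site had a median log2 fold of -0.36 over control. Anywhere in the transcript 34.7% hold the siRNA 2 site (4.17% to 18.1%), and 20 of those 25 genes hold it outside the 3' UTR, some of them also inside. For the genes without a site, and for how sites outside the 3' UTR would act, no explanation was tested.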
